A study of Mus musculus with 36 samples.

How the data were processed

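Mouse chromatin was analysed by ChIP-chip on 36 Agilent promoter arrays, 12 for each of H3K4me2, H3K9me2 and H3K27me3. Each mark was measured in ES cells, Flk1-positive mesodermal cells differentiated from ES cells on OP9 stroma, and nuclear-transfer TS cells, each as WT and as Dnmt1/Dnmt3a/Dnmt3b TKO. The 18 groups hold 2 arrays each. ChIP DNA was labelled with Cy5 and input DNA, digested with micrococcal nuclease, with Cy3, without dye swaps. Groups were taken from the sample titles. The labels do not state whether replicates are separate cultures.

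Per the file headers, the log10 values of each array file were made by the authors with Agilent Feature Extraction 10.5.1.1 as the log10 ratio of the ChIP over the input processed signal. Per the file headers, the intensity values of both channels had been detrended, corrected for a background estimated from negative controls, and dye-normalised linearly within the array, with surrogates in place of signals not above background. The deposited table of the series holds log2 values, which were checked to be the log10 ratios on a log2 scale for 91894 probes. Each array has 105072 spots and 99122 non-control probes of 45 to 60 bases, with positions on NCBI37 (mm9) as deposited.

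For each array the log2 ratio of the processed ChIP over input signal was taken, probes with an outlier mark were left out, and the array's median over probes was subtracted. Subtraction of the median removes any change of a mark's level over the whole genome. Probes were averaged per gene over the gene name in the files, with a minimum of 3 probes, which gave 12642 genes with a median of 5 probes over a median span of 1.14 kb. Of 14309 gene names, 11329 were current symbols in the reference (GRCm38.p6, used for names alone), 2127 were updated through a synonym and 853 were kept as deposited. Left out were 405 probes that name no gene, 267 without a position, genes under the probe minimum and 3 gene names with probes on several chromosomes.

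Models were fitted with limma 3.58.1 in R 4.3.3, with the data.table package in version 1.17.8 for reading and joining files. For each mark the 12 arrays were fitted as 6 group means with 1 variance per gene and empirical Bayes moderation. The contrasts were TKO minus WT in each cell type, Flk1 minus ES and TS minus ES in WT cells, and an F test of the interaction of genotype and cell type. A second model with cell type and genotype as terms gave the average genotype effect. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes within a contrast and a threshold of 0.05. The spread of arrays was compared with a two-sided exact permutation test within cell type over 216 arrangements.

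Lists of germline, 2-cell-stage, imprinted, developmental, Hox, pluripotency, trophoblast, Flk1+ mesoderm, stromal, endoderm, neural, housekeeping and tissue-restricted genes were fixed before the data were examined, as were the groups, contrasts, tests, naming rule and most alternatives. Measured members numbered 29 of 40, 2 of 22, 29 of 47, 39 of 64, 19 of 39, 29 of 34, 28 of 42, 30 of 44, 31 of 34, 26 of 30, 14 of 30, 32 of 40 and 15 of 52, in that order. Lists were tested against all other genes with camera at a preset correlation between genes of 0.01, and with camera at an estimated correlation, and against no change with fry, each adjusted over all lists and contrasts of a family. The genes eligible for naming were, per contrast, the 10 largest rises and 10 largest falls among genes that passed with both arrays of one group above both of the other, up to 4 members of each list, and a short set of key regulators. Of these the text leaves out genes of dim signal and, for length, others.

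The alternatives were normexp background correction with an offset of 50, arrays scaled to the same median absolute deviation, the deposited series table (11977 genes), the median over probes, probes well above background in the input on all arrays (82230 probes, 10694 genes), the replicate number as a block, slides as random blocks, a fit to the 2 groups compared, and each array left out in turn. Scan day as a block, list shifts within scan days, values relative to each array's median over genes, and crossed replicate numbers as a block were added after the data were seen. The last did not apply, since same-numbered arrays did not deviate against each other.

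The fits were tested on simulated data with the spread of these arrays, in which 50 genes were changed at each of 4 sizes. At changes of 0.25, 0.5, 1 and 2 on the log2 scale, the ES contrast recovered 6, 26, 44 and 50 genes for H3K4me2, 14, 35, 47 and 49 for H3K9me2, and 3, 24, 45 and 50 for H3K27me3, with 8, 10 and 10 false calls. The average genotype effect recovered 31, 41, 50 and 50 genes for H3K4me2, 35, 47, 50 and 50 for H3K9me2, and 17, 44, 50 and 50 for H3K27me3, with 10, 17 and 4 false calls. The interaction test recovered 0, 7, 34 and 49 genes for H3K4me2, 1, 21, 42 and 48 for H3K9me2, and 0, 4, 31 and 48 for H3K27me3, with 3, 2 and 2 false calls. Both camera and fry called the 1 list of 30 genes raised by 0.5 in each mark, with 0 false calls. Noise was drawn independently for each gene. These runs therefore cannot show how camera at the preset correlation behaves where genes vary together.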

Results

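Chromatin immunoprecipitation followed by promoter microarray hybridisation (ChIP-chip) was used to map 3 histone H3 modifications in mouse cells with and without DNA methylation. The modifications were H3K4me2, found at active and poised promoters, H3K9me2, a mark of silent chromatin, and H3K27me3, laid down by Polycomb complexes. Each was profiled in embryonic stem (ES) cells, in mesodermal cells sorted for the receptor Flk1, and in trophoblast stem (TS) cells made by nuclear transfer. Wild-type (WT) cells were set against cells that lack the DNA methyltransferases Dnmt1, Dnmt3a and Dnmt3b (triple knockout, TKO). The 36 arrays form 18 groups of 2 arrays, so the number of arrays limits the precision, and the labels do not state that replicates were separate cultures. The p values therefore measure the spread between arrays, which may be technical in part.

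Signal was above background at 85.9% to 99.2% of probes in the input channel and at 89.2% to 98.8% in the ChIP channel, depending on the array. Replicates correlated across genes with r from 0.994 to 0.997 for H3K4me2, from 0.960 to 0.978 for H3K9me2 and from 0.986 to 0.995 for H3K27me3. Values are log2(ChIP/input) relative to the array's median over probes, averaged over the probes of a gene, for 12642 genes. Changes are TKO minus WT or cell type minus ES on that log2 scale. Adjusted p values come from limma with Benjamini-Hochberg correction. For every gene named with a rise or a fall, both arrays of one group lay above both arrays of the other. Positions are on NCBI37 (mm9).

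The promoter regions of the targeted genes themselves did not move in 1 direction. Of 27 tests at Dnmt1, Dnmt3a and Dnmt3b, 13 passed, 6 of them at Dnmt3a, where H3K27me3 rose by 0.75 in Flk1 and 0.61 in TS cells. At the same gene H3K4me2 changed by -0.62 in Flk1 cells, and H3K9me2 changed by 0.32 in ES, -0.27 in Flk1 and -0.39 in TS cells. With normexp background correction 5 of the 6 no longer passed, all but H3K27me3 in Flk1 cells. These probes cover promoters, and their relation to the deleted part of each gene is not known, so they check nothing about the knockout.

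**Figure D1:**
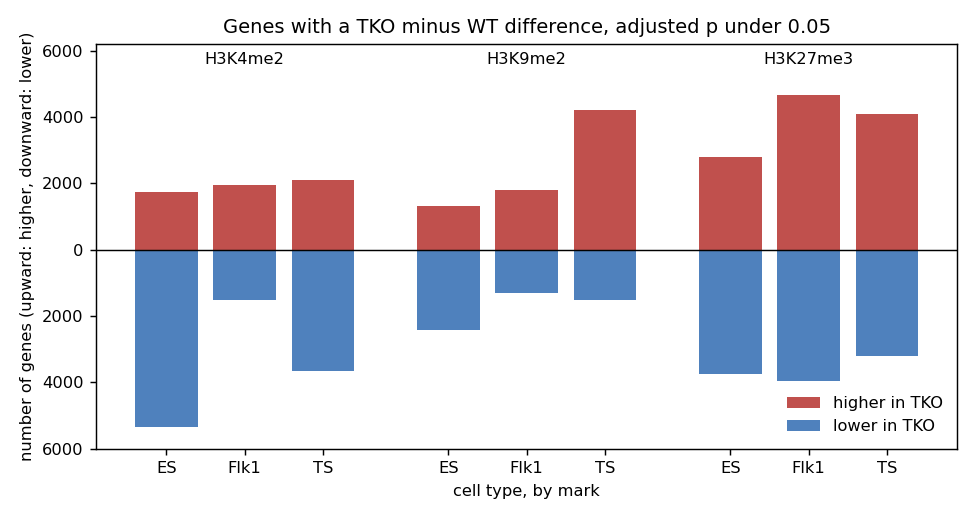
Numbers of genes whose ChIP/input ratio was higher (upward bars) or lower (downward bars) in TKO than in WT cells at an adjusted p under 0.05, for 3 marks in 3 cell types, out of 12642 genes. H3K4me2 in ES cells had 1752 genes higher and 5356 lower, and H3K9me2 in TS cells 4220 higher and 1501 lower.

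The first comparison asked how H3K4me2 at promoters differs in ES cells without DNA methylation. Most differences were small falls, among them most housekeeping genes, while 251 of the 315 changes over 1 on the log2 scale were rises. Mir122, a liver microRNA gene, rose by 2.84 ± 0.091 (SE), and Tlr4, the receptor for bacterial lipopolysaccharide, by 2.26. Sprr1a, a precursor of the skin barrier, rose by 2.18, C3ar1, a complement receptor, by 1.99, the antigen-presenting gene Mr1 by 1.92 and the B cell gene Cd19 by 1.88. The falls included Fam91a1 (-2.31), the protein repair gene Pcmtd1 (-2.03), Zfp560 (-1.85) and Eif2s1, a subunit of translation initiation factor eIF2 (-1.29). Of the housekeeping genes, 0 of 32 rose, 24 fell and 8 did not pass (0 and 26 adjusted over the list alone), among them the chaperonin genes Cct2 (-1.03) and Cct5 (-0.81), the splicing gene Snrpd3 (-0.92) and the ribosomal gene Rpl4 (-0.76). The list fell against other genes (adjusted p = 0.00496 by camera and adjusted p = 0.695 with an estimated correlation).

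Several lists lay above other genes. Among them were the Flk1+ mesoderm list (median 0.39) and the stromal list (0.26), which turned with arrays scaled to the same spread. Of the Hox genes, which pattern the body axis, 10 of 19 rose, 4 fell and 5 did not pass (10 and 4 adjusted over the list alone), with Hoxc9 at 1.17 and Hoxd9 at 0.74 (adjusted p = 4.8e-04 by camera and adjusted p = 0.695 with an estimated correlation). Among imprinted genes, 13 of 29 rose, 5 fell and 11 did not pass (13 and 5 adjusted over the list alone), led by Impact (0.72, but 0.60, adjusted p = 0.0581, with the median over probes), Mest (0.68) and Plagl1 (0.65) (adjusted p = 4.5e-04 by camera and adjusted p = 0.197 with an estimated correlation). Of the trophoblast genes, 13 of 28 rose, 6 fell and 9 did not pass (14 and 6 adjusted over the list alone), among them the keratin genes Krt8 (1.05) and Krt18 (0.77) and the placental gene Plac1 (1.06) (adjusted p = 4.5e-04 by camera and adjusted p = 0.790 with an estimated correlation). Of the endoderm genes, 12 of 26 rose, 2 fell and 12 did not pass (12 and 2 adjusted over the list alone), with the apolipoprotein gene Apoa1 at 0.90 (adjusted p = 7.1e-05 by camera and adjusted p = 0.790 with an estimated correlation). Of the developmental regulators with Polycomb marks, 12 of 39 rose, 7 fell and 20 did not pass (12 and 7 adjusted over the list alone) (adjusted p = 0.00295 by camera and adjusted p = 0.790 with an estimated correlation). The germline list had no common direction, since 9 of 29 rose, 9 fell and 11 did not pass (9 and 9 adjusted over the list alone). Its median (-0.089) and mean were below 0 while camera placed it above other genes without passing (adjusted p = 0.189 by camera and adjusted p = 0.942 with an estimated correlation). The testis dehydrogenase gene Ldhc rose by 1.00 and Mov10l1, of the piRNA pathway, by 0.93, while the testis helicase gene D1Pas1 (-0.92) and the meiotic entry gene Stra8 (-0.96) fell. Of the pluripotency genes, 4 of 29 rose, 15 fell and 10 did not pass (4 and 15 adjusted over the list alone). The list did not pass (adjusted p = 0.456 by camera and adjusted p = 0.942 with an estimated correlation). Pou5f1, which encodes Oct4, changed by -0.37 (but -0.12, adjusted p = 0.149, with arrays scaled to the same spread), Jarid2, a Polycomb cofactor gene, by -0.46 and Dppa3, an oocyte and early embryo gene, by 0.66.

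H3K4me2 differed at 7108 of 12642 genes in ES cells, 1752 higher and 5356 lower, and the median over all genes was -0.20. In values relative to each array's median over genes in place of probes, 45.7% of the called genes were higher against 24.6%, and 42.6% were in the deposited log ratios, so the split between rises and falls depends on the zero point. The count was 3398 with normexp background correction and 7352 with scan day in the model. Under the former Pcmtd1 (-1.22, adjusted p = 0.0502), Rpl4 (-0.31), Mov10l1 (0.47) and Dppa3 (0.35) no longer passed. The labels give different media for WT and TKO ES cells, a serum replacement for WT and fetal calf serum for TKO, so genotype and medium cannot be separated in this or any ES comparison. Within the 2 scan days that held both genotypes, the housekeeping list lay below other genes by a median of -0.24 and -0.16 and the Hox list above them by 0.68 and 0.45, and the germline list changed side (0.33 and -0.030).

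In Flk1 cells H3K4me2 rose at most germline genes on the list. Asz1, a germ cell gene of the piRNA pathway (chromosome 6, 18058771 to 18059855), rose by 4.21 ± 0.12 (SE), from -4.95 ± 0.076 (SD, n = 2) in WT to -0.74 ± 0.20 in TKO cells. Slc25a31, the testis form of the ADP/ATP carrier, rose by 3.63, Sycp1, which builds the synaptonemal complex, by 2.94, and the meiotic gene Tex11 by 2.81. The testis histone genes H2bc1 (4.22) and H2ac1 (3.85) and the testis cytochrome oxidase gene Cox7b2 (4.14) also rose, with Mia2 (4.71) and Drosha, the nuclease of microRNA processing (3.70). Of the germline genes with methylated promoters, 24 of 29 rose, 0 fell and 5 did not pass (24 and 0 adjusted over the list alone), with a median change of 1.28 (adjusted p = 9.7e-20 by camera and adjusted p = 0.682 with an estimated correlation). Dazl, a germ cell RNA-binding protein gene, rose by 0.57.

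Among imprinted genes in Flk1 cells, 11 of 29 rose, 7 fell and 11 did not pass (11 and 8 adjusted over the list alone), led by Mest (1.33), Zrsr1 (1.28), Sgce (1.28) and Impact (1.19), and the list did not pass (adjusted p = 0.189 by camera and adjusted p = 0.695 with an estimated correlation). Of the genes restricted to tissues outside these cells, 6 of 15 rose, 1 fell and 8 did not pass (7 and 1 adjusted over the list alone), with the pituitary gene Gh at 1.26 (adjusted p = 0.0438 by camera and adjusted p = 0.927 with an estimated correlation). Single lineage genes rose as well, from lists that did not pass: Afp, the fetal serum protein of endoderm (2.21), Emcn of endothelium (1.74), Tcl1 (1.43) and Dppa3 (1.03) of pluripotent cells, Hoxc8 (1.34) and the trophoblast homeobox gene Rhox6 (0.90, but 0.35, adjusted p = 0.259, with the median over probes). Of the pluripotency genes, 3 of 29 rose, 6 fell and 20 did not pass (4 and 7 adjusted over the list alone), with a median below 0 and a mean above it (adjusted p = 0.554 by camera and adjusted p = 0.942 with an estimated correlation, below other genes). Of the trophoblast genes, 4 of 28 rose, 8 fell and 16 did not pass (4 and 10 adjusted over the list alone) (adjusted p = 0.111 by camera and adjusted p = 0.927 with an estimated correlation). The falls were smaller, at Moxd2 (-2.45, but -0.69, adjusted p = 0.197 with normexp background correction), the oocyte gene Padi6 (-1.39), the keratin gene Krt7 (-1.08) and Pou5f1 (-0.38). Across all genes 3441 passed, 1939 higher and 1502 lower, and of the changes over 1 on the log2 scale 492 were rises and 42 falls. With normexp background correction the median over all genes was 0.13 and 79.9% of the called genes were higher against 56.3%. All arrays of this comparison were scanned on the same day, and without TKO replicate 1 the count was 2083.

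**Figure D2:**
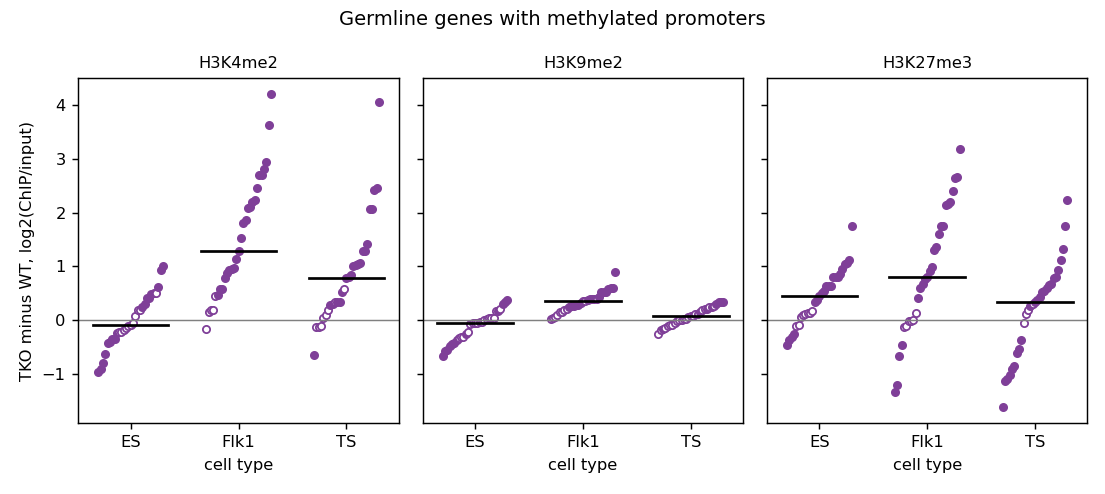
TKO minus WT change of log2(ChIP/input) for the 29 measured germline genes with methylated promoters, by mark and cell type, sorted within each cell type. Filled points passed at an adjusted p under 0.05, open points did not, and black lines are medians, which for H3K4me2 were -0.089 in ES, 1.28 in Flk1 and 0.79 in TS cells.

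In TS cells the germline rise of H3K4me2 came with large changes at imprinted genes in both directions. Asz1 rose by 4.06 ± 0.12 (SE), the meiotic gene Fkbp6 by 2.46, the testis tubulin gene Tuba3b by 2.42, Ldhc by 2.07 and Dazl by 0.83. Of the germline genes, 20 of 29 rose, 1 fell and 8 did not pass (22 and 1 adjusted over the list alone) (adjusted p = 7.2e-10 by camera and adjusted p = 0.695 with an estimated correlation). Dlk1, a paternally expressed Notch family ligand (chromosome 12, 110686405 to 110694033), rose by 3.62 ± 0.085 (SE), Nnat by 3.61 and the retrotransposon-derived placental gene Rtl1 by 2.76. Igf2, the fetal growth factor (chromosome 7, 149838505 to 149850738), changed by -3.00, from 0.85 ± 0.030 (SD, n = 2) in WT to -2.15 ± 0.010 in TKO cells. Of the imprinted genes, 17 of 29 rose, 8 fell and 4 did not pass (17 and 10 adjusted over the list alone) (adjusted p = 2.4e-04 by camera and adjusted p = 0.197 with an estimated correlation).

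Genes outside the lists gave the largest changes in TS cells. Rises came at Arhgap10, a Rho GTPase-activating gene (4.43), the cadherin gene Cdh4 (4.37), the ciliary gene Nphp4 (4.19), Mia2 (4.16) and the DNA repair gene Mgmt (4.06). Falls came at Dpp10 (-5.34 ± 0.095 (SE); chromosome 1, 125941824 to 125943104), the amino acid transporter gene Slc6a15 (-4.53), Lurap1l (-4.47), the prostaglandin-degrading gene Hpgd (-4.24) and the axon guidance receptor gene Robo2 (-3.94). Of the Hox genes, 3 of 19 rose, 10 fell and 6 did not pass (3 and 10 adjusted over the list alone), with Hoxb5 at -1.53 and Hoxb4 at -1.36, and the list missed the threshold (adjusted p = 0.0518 by camera and adjusted p = 0.909 with an estimated correlation). Falls among developmental regulators included Isl1 (-1.55), Gsc (-1.02) and Gata6 (-0.86), and among trophoblast genes Dlx3 (-0.90) and Tfap2a (-0.94). Pou5f1 changed by -0.58. The mesoderm gene Tbx6 (2.08) and Tdgf1, a Nodal co-receptor of pluripotent cells (1.77), rose. Of the tissue-restricted genes, 7 of 15 rose, 2 fell and 6 did not pass (7 and 2 adjusted over the list alone), among them Krt5 of skin (1.75) and Cryaa of the lens (1.70) (adjusted p = 0.00142 by camera and adjusted p = 0.790 with an estimated correlation). In total 5764 genes passed, 2110 higher and 3654 lower, and 2381 with normexp background correction, where Dazl (0.62, adjusted p = 0.0935) no longer passed. The count was 3505 without WT replicate 2 and 3513, with 47.2% higher against 36.6%, without TKO replicate 1. WT and TKO arrays were scanned on different days, so scan day and genotype cannot be told apart here.

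H3K9me2 in ES cells fell by the largest amounts at several receptor genes. The olfactory receptor genes Olfr1467 (-1.93 ± 0.19 (SE)), Olfr397 (-1.69) and Olfr1008 (-1.62) fell. So did Mrgprb8 (-1.87) and the mast cell receptor gene Mrgprb2 (-1.68) and the secretoglobin gene Scgb2b24 (-1.56). Some imprinted genes fell, with Mest (-0.85), Snrpn (-0.85), Sgce (-0.77) and Mcts2 (-0.75) in front. Of that list, 2 of 29 rose, 12 fell and 15 did not pass (3 and 14 adjusted over the list alone) (adjusted p = 0.0398 by camera and adjusted p = 0.695 with an estimated correlation). Rises were smaller, at the sperm gene Spata17 (1.20), Prtg (0.90), the synaptic gene Lrrtm2 (0.99) and Lect2 (0.98).

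Of the trophoblast genes in ES cells, 10 of 28 rose, 1 fell and 17 did not pass (12 and 1 adjusted over the list alone), among them Rhox9 (0.58), Krt7 (0.46) and Elf5, a key trophoblast transcription factor (0.36) (adjusted p = 1.5e-04 by camera and adjusted p = 0.695 with an estimated correlation). Of the tissue-restricted genes, 8 of 15 rose, 1 fell and 6 did not pass (10 and 3 adjusted over the list alone), with the fibrinogen gene Fgb at 0.73 and Cd19 at 0.58 (adjusted p = 4.5e-04 by camera and adjusted p = 0.695 with an estimated correlation). Of the endoderm genes, 7 of 26 rose, 0 fell and 19 did not pass (7 and 0 adjusted over the list alone), led by Hnf4a, a liver regulator (0.45) (adjusted p = 0.00105 by camera and adjusted p = 0.695 with an estimated correlation). Of the Flk1+ mesoderm, blood and endothelial genes, 9 of 30 rose, 3 fell and 18 did not pass (11 and 3 adjusted over the list alone) (adjusted p = 0.00248 by camera and adjusted p = 0.695 with an estimated correlation). Of the Hox genes, 0 of 19 rose, 4 fell and 15 did not pass (0 and 4 adjusted over the list alone), with Hoxd13 at -0.56 and Hoxa6 at -0.45 (adjusted p = 0.0183 by camera and adjusted p = 0.923 with an estimated correlation). The ubiquitin gene Ubc (-0.98), the glycolytic gene Pgk1 (-0.61), Dppa3 (-0.83), Asz1 (-0.66) and Slc25a31 (-0.56) fell. The count was 3711, of which 1306 were higher and 2405 lower. In values relative to each array's median over genes, 48.4% of the called genes were higher against 35.2%. Named genes that no longer passed under normexp background correction were Mcts2, Snrpn, Spata17, Lrrtm2, Rhox9, Krt7, Elf5, Fgb, Cd19, Hoxd13, Hoxa6, Pgk1, Dppa3 and Slc25a31. Within the 2 scan days that held both genotypes, the tissue-restricted list lay above other genes by 0.23 and 0.35, and the imprinted list below them (-0.099 and -0.040). The count was 3480 with scan day in the model, 219 (25.1% higher) with normexp background correction, 756 in a fit to the 4 ES arrays alone, and 2304 or 2348 without 1 of the TKO replicates.

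In Flk1 cells H3K9me2 moved little: 3126 genes passed, 1809 higher and 1317 lower, and 0 of them by more than 1 on the log2 scale. The rises included Fkbp6 (0.89 ± 0.091 (SE)), D1Pas1 (0.60), Tuba3b (0.60) and Slc25a31 (0.57) of the germline, and Serinc5, a membrane gene (0.84), Ormdl2 (0.80) and Prepl (0.78). Of the germline list, 19 of 29 rose, 0 fell and 10 did not pass (21 and 0 adjusted over the list alone) (adjusted p = 3.9e-08 by camera and adjusted p = 0.695 with an estimated correlation). Relative to other genes the list's ratio changed by 0.29, its ChIP channel alone by 0.047 and its input channel by -0.18. Falls included the centrosomal gene Cep295 (-0.99), the platelet gene Gp5 (-0.90), Zbtb18 (-0.84) and the secretory pathway gene Sec16a (-0.81). Of the Hox genes, 0 of 19 rose, 8 fell and 11 did not pass (3 and 11 adjusted over the list alone), with Hoxa6 (-0.79), Hoxb5 (-0.70) and Hoxc10 (-0.64) in front (adjusted p = 1.0e-03 by camera and adjusted p = 0.790 with an estimated correlation). Among trophoblast genes, 2 of 28 rose, 10 fell and 16 did not pass (4 and 12 adjusted over the list alone), with Krt7 at -0.29 (adjusted p = 0.00496 by camera and adjusted p = 0.706 with an estimated correlation). Among endoderm genes, 0 of 26 rose, 7 fell and 19 did not pass (1 and 7 adjusted over the list alone), with the chemokine receptor gene Cxcr4 at -0.33 (adjusted p = 0.00496 by camera and adjusted p = 0.695 with an estimated correlation). Of the stromal and fibroblast genes, 4 of 31 rose, 9 fell and 18 did not pass (4 and 11 adjusted over the list alone), with the collagen gene Col1a1 at -0.37 (adjusted p = 0.00496 by camera and adjusted p = 0.695 with an estimated correlation). The heart and limb regulator Tbx5 (-0.54), the Nodal antagonist gene Lefty2 (-0.69), Pou5f1 (-0.40), Eng (-0.38) and Mest (-0.43) fell, and Impact rose by 0.59. The count did not hold. It was 2 with normexp background correction, where Cep295 alone of the genes named here passed, and 0 with scan day in the model, while 5003 genes had an unadjusted limma p under 0.05 without that term. With scan day in the model the estimate rests on the 1 TKO and 2 WT arrays of the shared day. The sizes then stayed close, as at Serinc5 (0.83, adjusted p = 0.0557), Cep295 (-0.96, adjusted p = 0.0557) and Hoxb5 (-0.58, adjusted p = 0.0864), so the count of 0 does not show that scan day gave these changes. The germline list then lay above other genes by 0.20 against 0.29, and the Hox list below them (-0.20 against -0.28). In the deposited log ratios 43.4% of the called genes were higher against 57.9%. The count was 587 and 1191 without WT replicate 1 or 2 and 501 without TKO replicate 2.

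In TS cells H3K9me2 rose more often than it fell, and 3 of the genes named here with a rise, Lurap1l, Igf2 and Isl1, are also named above with a fall of H3K4me2. Lurap1l rose by 1.34, the growth factor protease gene Pappa by 1.36 ± 0.094 (SE) and Igf2 by 1.15. The neural cadherin gene Celsr3 (1.45), the neural membrane gene Slitrk5 (1.17), the forebrain regulators Six3 (0.92) and Emx2 (0.70) and Isl1 (0.90) rose as well. Falls included Gp5 (-1.40), Olfr1443 (-1.14), Olfr770 (-1.10), the chromatin remodeller gene Pbrm1 (-0.94), the blood and endothelial genes Cd34 (-0.72) and Eng (-0.66), and the stromal genes Pparg (-0.65) and Bgn (-0.46). Of the imprinted genes, 6 of 29 rose, 10 fell and 13 did not pass (6 and 10 adjusted over the list alone), with Grb10 up by 0.46 and Tssc4 (-0.50) and Nnat (-0.76) down (adjusted p = 0.00818 by camera and adjusted p = 0.592 with an estimated correlation), a direction that turned with normexp background correction. Among developmental regulators, 20 of 39 rose, 2 fell and 17 did not pass (20 and 2 adjusted over the list alone), without the list passing (adjusted p = 0.0909 by camera and adjusted p = 0.942 with an estimated correlation). Of the housekeeping genes, 14 of 32 rose, 0 fell and 18 did not pass (14 and 0 adjusted over the list alone), with Psmb4 at 0.40 (adjusted p = 0.0462 by camera and adjusted p = 0.790 with an estimated correlation), a direction that turned with normexp background correction and with arrays scaled to the same spread. Of the stromal and fibroblast genes, 5 of 31 rose, 11 fell and 15 did not pass (7 and 11 adjusted over the list alone), below other genes here and above them with normexp background correction (adjusted p = 0.0129 by camera and adjusted p = 0.782 with an estimated correlation). In total 5721 genes passed, 4220 (73.8%) higher and 1501 lower. The median over all genes was 0.13. This split and the list counts may therefore depend on the zero point, which was not tested here. The count was 692 with normexp background correction, with 56.6% higher, and 3471 with arrays scaled to the same spread. Under the former Six3 (0.17, adjusted p = 0.441), Slitrk5, Cd34, Eng, Bgn, Grb10 and Tssc4 no longer passed. The count was 3739, 3534 and 3289 without WT replicate 1, WT replicate 2 or TKO replicate 2, and scan day and genotype cannot be told apart here.

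H3K27me3 rose in TKO ES cells at developmental genes that carried it in WT, where the list's median was 2.07 on the log2 scale. Of the developmental regulators with Polycomb marks, 27 of 39 rose, 0 fell and 12 did not pass (28 and 0 adjusted over the list alone), among them the signalling genes Wnt3 (0.97) and Ihh (0.85) and the transcription factor genes Hand2 (0.93) and Gata6 (0.85) (adjusted p = 1.9e-04 by camera and adjusted p = 0.927 with an estimated correlation). Of the Hox genes, 15 of 19 rose, 0 fell and 4 did not pass (15 and 0 adjusted over the list alone), with Hoxa4 at 1.02, Hoxa9 at 1.01 and Hoxb5 at 0.97 (adjusted p = 1.5e-04 by camera and adjusted p = 0.790 with an estimated correlation). Large rises came at Arhgap10 (2.74 ± 0.083 (SE)), Mitf, the melanocyte regulator (2.47), Glis3 (2.19), Prtg (2.17) and the glycan-processing gene Man2a2 (2.01). Falls came at Zfp318 (-2.68), Ica1l (-2.68), Naif1 (-2.63), Epop, a Polycomb partner gene (-2.39), Id2 (-2.15), Cd34 (-1.97) and the lymphoid regulator Ikzf1 (-1.42).

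Further lists in ES cells held more rises than falls. Of the trophoblast genes, 17 of 28 rose, 5 fell and 6 did not pass (17 and 5 adjusted over the list alone), with the gap junction gene Gjb5 at 1.58 and Elf5 at 1.05 (adjusted p = 0.00248 by camera and adjusted p = 0.927 with an estimated correlation). Of the endoderm genes, 16 of 26 rose, 3 fell and 7 did not pass (16 and 3 adjusted over the list alone), with Afp at 1.57 and Hnf4a at 1.38 (adjusted p = 0.00162 by camera and adjusted p = 0.790 with an estimated correlation). Of the germline genes, 17 of 29 rose, 4 fell and 8 did not pass (17 and 4 adjusted over the list alone), with D1Pas1 at 1.75 and the testis tubulin gene Tuba3a at 1.11 (adjusted p = 0.00105 by camera and adjusted p = 0.790 with an estimated correlation). Of the tissue-restricted genes, 8 of 15 rose, 2 fell and 5 did not pass (8 and 2 adjusted over the list alone), with the rhodopsin gene Rho at 1.35 and Krt14 of skin at 1.06 (adjusted p = 0.0171 by camera and adjusted p = 0.695 with an estimated correlation). Among neural genes, 4 of 14 rose, 2 fell and 8 did not pass (4 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.410 by camera and adjusted p = 0.942 with an estimated correlation). In total 6550 genes passed, 2802 higher and 3748 lower, and 1880 with normexp background correction, where Ica1l (-0.80, adjusted p = 0.0697) and Krt14 (0.53, adjusted p = 0.183) no longer passed. In values relative to each array's median over genes 55.6% of the called genes were higher against 42.8%. Scan day and genotype cannot be told apart here, since WT and TKO arrays were scanned on different days.

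In Flk1 cells H3K27me3 changed by more than 1 on the log2 scale at 2008 genes. Kank1, a cytoskeletal regulator (chromosome 19, 25482908 to 25484372), rose by 5.23 ± 0.14 (SE), from -1.46 ± 0.025 (SD, n = 2) to 3.76 ± 0.38. Man2a2 (4.34), the Notch coactivator gene Maml3 (4.10), the phosphatase gene Ptpn14 (4.03) and the phospholipase gene Plce1 (4.01) rose too. Slc6a15 (chromosome 10, 102829514 to 102830762) fell (-3.69 ± 0.10 (SE)), with Ankrd34a (-3.58), Vopp1 (-3.43) and the zinc finger gene Sall2 (-2.92). Of the germline genes, 19 of 29 rose, 4 fell and 6 did not pass (19 and 4 adjusted over the list alone), among them Sycp1 (3.18), the meiotic gene Hormad1 (2.67), Tuba3b (2.65) and D1Pas1 (2.41) (adjusted p = 0.00162 by camera and adjusted p = 0.790 with an estimated correlation). Of the housekeeping genes, 19 of 32 rose, 0 fell and 13 did not pass (19 and 0 adjusted over the list alone), with Gpi1 of glycolysis at 1.33 and the ribosomal gene Rplp0 at 0.74 (adjusted p = 0.00496 by camera and adjusted p = 0.695 with an estimated correlation).

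Pluripotency genes were divided in Flk1 cells, where 8 of 29 rose, 13 fell and 8 did not pass (8 and 13 adjusted over the list alone), with Tcl1 at 3.32, Tdgf1 at -1.50 and Pou5f1 at -1.01 (adjusted p = 0.276 by camera and adjusted p = 0.942 with an estimated correlation). Among imprinted genes, 17 of 29 rose, 5 fell and 7 did not pass (18 and 5 adjusted over the list alone). Igf2 rose by 1.66, while the neuronal growth suppressor gene Ndn (-2.30) and Mkrn3 (-1.22) fell. The list did not pass (adjusted p = 0.0777 by camera and adjusted p = 0.927 with an estimated correlation). Falls reached the endothelial genes Cd34 (-2.04) and Esam (-1.40), the collagen gene Col1a2 (-2.05) and the mesenchymal regulator Twist1 (-1.42). Rho (2.39) and Krt14 (2.24) rose. In total 8605 genes passed, 4657 higher and 3948 lower, and 7614 with scan day in the model. On the shared scan day the germline list lay above other genes by 0.63 against 0.70, while the developmental list turned from 0.21 to -0.074, the neural from 0.15 to -0.14, the endoderm from 0.15 to -0.052 and the trophoblast list from 0.16 to -0.071. The count was 3666 with normexp background correction, and 37.9% of the called genes were higher in the deposited log ratios against 54.1%.

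In TS cells H3K27me3 changed by more than 1 on the log2 scale at 1636 genes, and none of the lists passed. Tshz2, a zinc finger gene, rose by 3.98 ± 0.15 (SE), Fmo9 by 3.86, the synaptic gene Igsf21 by 3.75 and the sorting receptor gene Sorcs3 by 3.04. Tbx5 (3.62), the head organiser gene Otx2 (2.25), the kidney regulator Wt1 (1.63), Gata6 (1.23) and Gata4 (1.05) rose among developmental regulators, and Eomes, a trophoblast stem cell regulator, fell (-1.17). Of that list, 19 of 39 rose, 8 fell and 12 did not pass (20 and 9 adjusted over the list alone) (adjusted p = 0.189 by camera and adjusted p = 0.942 with an estimated correlation). The replication-linked histone genes H4c12 (-4.70) and H1f5 (-4.38) fell, as did the neuronal membrane gene Gpm6a (-4.45), Wdr17 (-4.70) and Olfr303 (-4.59). Of the imprinted genes, 15 of 29 rose, 5 fell and 9 did not pass (15 and 5 adjusted over the list alone), with Dlk1 (3.37), Igf2 (3.24 ± 0.16 (SE)) and the deiodinase gene Dio3 (2.13) up and Ndn down (-3.32) (adjusted p = 0.189 by camera and adjusted p = 0.942 with an estimated correlation).

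Of the trophoblast genes in TS cells, 5 of 28 rose, 7 fell and 16 did not pass (5 and 7 adjusted over the list alone), with the matrix protease gene Mmp9 (2.02) and Dlx3 (1.47) up and the galectin gene Lgals3 down (-1.58) (adjusted p = 0.610 by camera and adjusted p = 0.942 with an estimated correlation). Of the germline genes, 16 of 29 rose, 9 fell and 4 did not pass (17 and 9 adjusted over the list alone), with D1Pas1 (2.25) and the piRNA gene Mael (1.76) up and the meiotic gene Tex15 down (-1.62) (adjusted p = 0.531 by camera and adjusted p = 0.942 with an estimated correlation). Relative to other genes this list's ratio changed by 0.24 (0.22 on the shared scan day), its ChIP channel alone by 0.018 and its input channel by -0.14. Vim, the mesenchymal filament gene (-1.92), and the pluripotency gene Nr0b1 (-1.99) fell, and Tcl1 (1.72) and Afp (1.68) rose. The count was 7288, 4096 (56.2%) higher and 3192 lower, and 5665 with scan day in the model. With normexp background correction it was 2286, of which 38.1% were higher.

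The cell types themselves were compared in WT cells, as a reference for the knockout effects. No scan day held WT arrays of ES and of another cell type for the same mark, so scan day and cell type cannot be told apart here. From ES to Flk1 cells H3K4me2 rose at mesodermal genes, among them Kdr, which encodes Flk1 (1.76), the cardiac regulators Gata4 (2.73 ± 0.082 (SE)), Hand2 (2.74) and Tbx5 (2.59), the gastrulation genes Mixl1 (1.82) and Eomes (1.50), the endothelial gene Cd93 (4.14) and Bmp5 (4.00). Of the Flk1+ mesoderm, blood and endothelial genes, 18 of 30 rose, 3 fell and 9 did not pass (18 and 3 adjusted over the list alone) (adjusted p = 1.2e-04 by camera and adjusted p = 0.607 with an estimated correlation). Of the stromal and fibroblast genes, which also mark the OP9 stroma these cells grew on, 22 of 31 rose, 2 fell and 7 did not pass (22 and 2 adjusted over the list alone), with Acta2 at 2.08 and Pdgfrb at 1.85 (adjusted p = 1.4e-05 by camera and adjusted p = 0.619 with an estimated correlation). The basement membrane gene Col4a2 rose by 2.12. Of the pluripotency genes, 1 of 29 rose, 19 fell and 9 did not pass (2 and 19 adjusted over the list alone), led by Tcl1 (-3.82), Zfp42 (-2.52) and Dppa4 (-2.44), with Pou5f1 at -0.59 (adjusted p = 1.0e-05 by camera and adjusted p = 0.468 with an estimated correlation). Of the germline genes, 0 of 29 rose, 26 fell and 3 did not pass (0 and 26 adjusted over the list alone), with D1Pas1 (-3.83), Sycp1 (-3.39) and Tex14 (-3.31) in front (adjusted p = 2.2e-11 by camera and adjusted p = 0.468 with an estimated correlation). Drosha (-4.84) and H2bc1 (-4.41) fell in WT Flk1 cells as well.

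H3K27me3 rose at most pluripotency genes. From ES to Flk1 cells 24 of 29 rose, 3 fell and 2 did not pass (24 and 3 adjusted over the list alone), with Utf1 at 4.51 ± 0.15 (SE), Sox2 at 3.92, Pou5f1 at 3.59, Gdf3 at 3.48 and the ES cell Ras gene Eras at 3.90 (adjusted p = 1.6e-07 by camera and adjusted p = 0.468 with an estimated correlation). Of the Hox genes, 17 of 19 rose, 0 fell and 2 did not pass (18 and 0 adjusted over the list alone), with Hoxc13 at 2.44 and Hoxa4 at 1.84 (adjusted p = 9.5e-06 by camera and adjusted p = 0.662 with an estimated correlation). Among neural genes, 12 of 14 rose, 2 fell and 0 did not pass (12 and 2 adjusted over the list alone), with the tubulin gene Tubb3 (2.88), Neurod1 (1.87) and the eye regulator Pax6 (1.58) (adjusted p = 0.00606 by camera and adjusted p = 0.721 with an estimated correlation). Mixl1 (-1.91), Eomes (-1.47), Zfp521 (-3.13), Sycp3 (-3.14), Sycp1 (-2.45) and Asz1 (-2.35) lost it. H3K9me2 rose at the protocadherin genes Pcdhb22 (2.21) and Pcdhga3 (2.00), at Epop (1.83), Hoxb5 (1.31) and Msx2 (1.20). It fell at Scgb2b24 (-1.54), Mrgprb8 (-1.52) and Olfr392 (-1.49). The germline list fell for H3K9me2 as well, where 4 of 29 rose, 22 fell and 3 did not pass (4 and 22 adjusted over the list alone), among them Tuba3b (-1.16), Slc25a31 (-1.12) and Fkbp6 (-1.06) (adjusted p = 1.9e-04 by camera and adjusted p = 0.662 with an estimated correlation). The numbers of genes that passed between WT Flk1 and ES cells were 7112 for H3K4me2, 8426 for H3K9me2 and 8061 for H3K27me3, and 4127, 3704 and 4638 with normexp background correction.

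Between WT ES and TS cells the trophoblast genes changed for H3K4me2 and H3K27me3. For H3K4me2, 24 of 28 rose, 1 fell and 3 did not pass (24 and 1 adjusted over the list alone), with Elf5 at 3.22 ± 0.11 (SE), Cdx2, a founder gene of the trophoblast lineage, at 1.66, Plac1 at 2.17, Krt8 at 1.66 and Hand1 at 1.53 (adjusted p = 3.1e-11 by camera and adjusted p = 0.468 with an estimated correlation). For H3K27me3 in the same list, 1 of 28 rose, 25 fell and 2 did not pass (1 and 25 adjusted over the list alone), led by Gata3 (-3.25), Krt18 (-3.16), Mmp9 (-3.03), Hand1 (-2.95), Elf5 (-2.11) and Cdx2 (-1.23) (adjusted p = 2.0e-07 by camera and adjusted p = 0.662 with an estimated correlation). H3K4me2 fell at the pluripotency genes Tdgf1 (-3.55), Spp1 (-3.45) and Dppa5a (-2.75). H3K27me3 rose at Pou5f1 (2.49) and Spp1 (2.49). Imprinted genes were lower for H3K4me2 in WT TS cells, where 5 of 29 rose, 24 fell and 0 did not pass (5 and 24 adjusted over the list alone), among them Dlk1 (-3.46), Snrpn (-3.10) and Nnat (-2.96) (adjusted p = 8.0e-04 by camera and adjusted p = 0.426 with an estimated correlation). Asz1 (-2.89), Tbx6 (-3.46), the synaptotagmin gene Syt4 (-5.29) and the neural splicing gene Srrm4 (-4.94) fell, and the macrophage receptor gene Csf1r rose by 3.77.

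H3K27me3 was also lower in WT TS than ES cells at Tbx5 (-3.78), Tshz2 (-3.69), Dlk1 (-3.12), Igf2 (-2.83) and Hoxa1 (-2.08). It was higher at Olfr794 (4.13), Olfr1494 (4.13), Lpar4 (4.08), Pparg (3.10) and Col3a1 (2.26). H3K9me2 rose in TS cells at Pcdha12 (2.17), Phox2b (1.76), Otx2 (1.62), Hnf1b (1.40), Hoxb4 (1.39) and Prrx1 (1.13). It fell at the actin gene Actg1 (-1.97), the translation factor gene Eif5a (-1.47), Olfr180 (-1.46), the ribosomal gene Rps18 (-0.80) and the polymerase gene Polr2a (-0.67). Under normexp background correction Eif5a (-0.040, adjusted p = 0.812), Rps18 (-0.24), Polr2a (-0.24) and Prrx1 (0.59) no longer passed. Of the developmental regulators, 24 of 39 rose, 7 fell and 8 did not pass (24 and 7 adjusted over the list alone) (adjusted p = 6.0e-09 by camera and adjusted p = 0.619 with an estimated correlation). The numbers of genes that passed were 7786 for H3K4me2, 7752 for H3K9me2 and 9088 for H3K27me3, and 4735, 2100 and 3789 with normexp background correction. For H3K27me3 55.0% of the called genes were then higher against 43.8%, and for H3K9me2 42.8% were higher in the deposited log ratios against 28.5%. Of 108 list tests between genotypes 37 passed, and of 72 between cell types 32 passed, and 0 of these held with an estimated correlation. The list of 2-cell-stage genes had 2 measured members and was not tested.

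Averaged over the 3 cell types, 6 TKO against 6 WT arrays, H3K4me2 differed at 4146 genes (1276 higher, 2870 lower), H3K9me2 at 517 (335 higher, 182 lower) and H3K27me3 at 6210 (3310 higher, 2900 lower). Called higher in all 3 cell types were 400 genes for H3K4me2, 67 for H3K9me2 and 1159 for H3K27me3, and called lower in all 3 were 313, 53 and 1250. Called in opposite directions in different cell types were 1465, 1872 and 2057. ES cells, whose media differed, enter all these counts. With scan day in the model the counts were 2797 for H3K4me2 and 4901 for H3K27me3. With normexp background correction they were 1972 for H3K4me2 and 2497 for H3K27me3, of which 37.9% were higher against 53.3%. In the deposited log ratios 42.4% of the called genes were higher for H3K4me2 against 30.8%, and 42.1% for H3K27me3. The H3K9me2 count was 10 with normexp background correction, 1 with scan day in the model and 142 (85.2% higher against 64.8%) with slides as random blocks, and between 92 and 899 when single arrays were left out, so no shared H3K9me2 effect is described by gene. For H3K4me2 the count was 2690 without TS WT replicate 2 and 2656 without TS TKO replicate 1.

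A limma F test of the interaction of genotype and cell type passed at 7125 genes for H3K4me2, 7169 for H3K9me2 and 8181 for H3K27me3. With normexp background correction it passed at 3619, 388 and 2703. It included ES cells, and single pairs were tested against them, so their differing media may contribute. For H3K4me2 it passed at 27 of 29 germline genes. Against ES cells the change was larger in Flk1 at 26 and smaller at 1, and in TS larger at 21 and smaller at 0. The F test passed at 25 of 29 imprinted genes. Against ES cells the change was larger in TS at 16 and smaller at 6, and in Flk1 larger at 11 and smaller at 7. For H3K27me3 it passed at 11 of 19 Hox genes, and the change was smaller than in ES cells at 6 members in Flk1 and 8 in TS cells. For H3K9me2 it passed at 15 of 19 Hox genes, and the change was larger in TS than in ES cells at 12 members.

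Correlations were computed across genes, which are not independent replicates, and carry no p value. Cell-type differences in WT and TKO cells correlated at r = 0.692 (rho = 0.605) for Flk1 and r = 0.685 (rho = 0.590) for TS cells in H3K4me2, at r = 0.714 (rho = 0.718) and r = 0.459 (rho = 0.410) in H3K9me2, and at r = 0.663 (rho = 0.577) and r = 0.713 (rho = 0.673) in H3K27me3. The knockout effects of different cell types gave lower values within each mark. This did not hold with normexp background correction, where H3K4me2 gave 0.554 for the effects in Flk1 and TS cells and 0.432 for the Flk1 cell-type differences. For H3K4me2 they correlated at r = 0.219 (rho = 0.0970) between ES and Flk1, 0.245 (rho = 0.222) between ES and TS, and 0.428 (rho = 0.339) between Flk1 and TS cells, and the first was 0.0134 with arrays scaled to the same spread. The same pairs gave -0.148 (rho = -0.170), -0.0246 (rho = -0.0857) and 0.199 (rho = 0.198) for H3K9me2, and 0.541 (rho = 0.482), 0.383 (rho = 0.396) and 0.397 (rho = 0.438) for H3K27me3. For H3K9me2, ES and TS turned to 0.258 and Flk1 and TS to -0.0112 with normexp background correction.

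Between marks, the knockout effects on H3K4me2 and H3K9me2 were opposed in TS cells (r = -0.362, rho = -0.444) and weakly positive in ES (0.200, rho = 0.199) and Flk1 cells (0.0794, rho = 0.0939). H3K4me2 and H3K27me3 gave 0.0424 (rho = 0.00015) in ES, 0.239 (rho = 0.146) in Flk1 and 0.0831 (rho = 0.00632) in TS cells, and H3K9me2 and H3K27me3 gave 0.290 (rho = 0.255), 0.0358 (rho = 0.0592) and 0.105 (rho = 0.0844). The relation in TS cells between H3K4me2 and H3K9me2 was -0.0888 with arrays scaled to the same spread. Noise in the input can be shared between marks, which would move their ratios the same way.

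The spread of H3K4me2 over genes was narrower in TKO than WT arrays. Its SD was 1.83 in TKO and 2.00 in WT arrays, a difference of -0.17 (exact permutation test within cell type, 216 arrangements, two-sided p = 0.00926, the smallest this design allows). For H3K9me2 the difference was -0.033 (exact permutation p = 0.380) and for H3K27me3 0.0063 (exact permutation p = 0.926). At the tenth of genes with the most H3K4me2 in WT cells, the median change was -0.49 in ES, -0.085 in Flk1 and -0.29 in TS cells. With arrays scaled to the same spread the ES value was -0.12 and the TS value -0.071. For H3K9me2 it was -0.33, 0.19 and -0.13, and for H3K27me3 0.077, -0.25 and -0.48, and with that scaling the H3K9me2 value in TS cells and the H3K27me3 value in Flk1 cells turned positive. The genes were chosen on one WT replicate and the change was taken against the other. Because each array is centred, a loss or gain of a mark over the whole genome cannot be seen.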

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

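The test of the input signal at germline promoters was chosen after its result was seen, values relative to each array's median over genes were added after the data were seen, and the other tests here were set before their results were seen.

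The TKO minus WT difference varied between cell types, by an interaction test, at 7125 genes for H3K4me2, 7169 for H3K9me2 and 8181 for H3K27me3.

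In the input channel, which the comparisons use only inside a ratio, the medians of some chromosomes differed between TKO and WT lines, with all 6 TKO arrays of a cell type on one side of all 6 WT arrays. Shifts over 0.1 on the log2 scale, relative to the array, were -0.15 (ES) and -0.13 (Flk1) on chromosome 8 and 0.20 (Flk1) on 11. In TS cells they were 0.10 on chromosome 1, 0.47 on 8, -0.33 on 11 and 0.22 on 14. Some covered part of a chromosome. In ES and Flk1 cells chromosome 8 was lower from 0 to 10 Mb (-0.46 and -0.43) and beyond 90 Mb. In TS cells chromosome 11 was lower up to 100 Mb (-0.62 to -0.29) and not beyond (0.015 to 0.073). Its level was 0.44 in WT TS, 0.32 in TKO Flk1 and 0.11 to 0.135 in all other cells, so WT TS stood highest. Shifts under 0.1 with the same separation of arrays were found on chromosome 17 in ES (0.056), Flk1 (0.068) and TS cells (0.040), on chromosome 3 in ES cells (-0.033), and in TS cells on chromosomes 2 (-0.019), 5 (0.046), 6 (-0.047), 13 (-0.042) and X (-0.054).

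The chromosome 8 shift in TS cells came with shifts of the ChIP channel that were at least 0.857 of its size in each mark (0.806 to 1.27 over pairs of arrays). A GC trend in the probes is argued against, since 0.952 of the shift was left once that trend was removed (0.906 to 0.983). All 6 of 6 TKO arrays lay above every WT array, with means of 0.53 ± 0.0098 (SD) in TKO and 0.062 ± 0.0088 in WT arrays. Chromosomes were listed here by that same separation, so the count is no separate test of a few deviating arrays. A candidate explanation that stays open is more DNA copies of most of chromosome 8 in the TKO than the WT TS line. The ChIP channel values fit it. The input level of chromosome 8 relative to other autosomes was 0.53 in TKO TS, 0.50 in WT ES and 0.49 in WT Flk1 cells. It was 0.35 in TKO ES and TKO Flk1 cells and 0.062 in WT TS cells. The shift therefore does not show which line changed, and WT TS and WT ES cells differed as well. The ChIP over input ratio on chromosome 8 moved by 0.084 for H3K4me2, -0.038 for H3K9me2 and -0.062 for H3K27me3. On chromosome 11 in TS cells, with an input shift of -0.33, the ChIP channel moved by -0.39, -0.21 and -0.20 in that order and the ratio by -0.070, 0.094 and 0.17.

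The germline list rose for H3K9me2 over input in TKO Flk1 cells by a median of 0.29 relative to other genes. The ChIP channel alone changed by 0.047 (-0.043 to 0.14 over pairs of arrays), and the input channel by -0.18. A candidate explanation is therefore lower input signal at these promoters in place of more H3K9me2. The GC and CpG content of the probes is argued against, since a change of 0.25 on the log2 scale out of 0.29 was left once those trends were removed (0.19 to 0.32). Whether H3K9me2 itself rose at these promoters stays open.

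H3K4me2 in ES cells fell at more genes than it rose at, with 24.6% of the called genes higher. With arrays scaled to the same spread, which keeps the zero point, 24.4% were higher. Relative to each array's median over genes 45.7% were higher. Neither value can decide on a narrower spread of the TKO arrays, because the zero point itself sets the split. Either choice of it removes a change of the mark's level over the whole genome. The culture medium, for which the labels of WT and TKO ES cells differ, stays open as well, so a biological reading was not tested.

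For the average genotype effect, chance differences between arrays can be excluded for H3K4me2, where 1 of 100 regroupings balanced within cell type, the real one, gave as many as the 4146 genes and the highest other gave 753. The same holds for H3K27me3, with 1 of 100, a real value of 6210 and a highest other of 818. Chance differences between cell lines are not covered, since only 4 regroupings keep the 2 arrays of each group together, and the labels do not state whether these are separate cultures. For H3K9me2 2 of 100 regroupings gave as many as the real 517 genes and the highest other gave 3118. That grouping keeps the genotypes apart in each cell type but turns ES cells against the others, and a count this far above the real one points to a structure of the samples. Among all 108 possible regroupings 3 gave as many, and 1 of these, with 592 genes, mixes the genotypes. What gives these counts for H3K9me2, ES media included, stays open.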

How the results depend on the processing

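Scan day as a block and values relative to each array's median over genes were chosen after the data were seen. All 337 named changes kept their direction under every alternative that gave a value for them. Of these 337, 60 no longer passed with normexp background correction and 3 with each of the median over probes, slides as random blocks and the fit to the 2 groups alone, and with scan day as a block 24 of 140 no longer passed. With arrays scaled to the same spread 1 was lost. Without single arrays the losses were 7 of 24 for Flk1 TKO replicate 2 and 7 of 35 for Flk1 WT replicate 1 of H3K9me2, 1 each for ES WT replicate 1 and ES TKO replicate 1 of H3K4me2, and 1 for ES TKO replicate 1 of H3K9me2. H3K9me2, the mark with the narrowest range over genes, was the one whose counts fell to 2, 10 and 219 under normexp background correction. Where ChIP or input signal is close to background the ratio is less certain, which limits dim probes most. The cause of these dependences was not tested. The values below are those that moved by more than 1.5 times (counts), by more than the spread between replicates (other values) or in direction.

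With normexp background correction the number of called genes for H3K4me2 was 3398 in ES, 2381 in TS and 1972 for the average effect. Flk1 against ES gave 4127, TS against ES 4735 and the interaction 3619. For H3K9me2 it was 219 in ES, 2 in Flk1, 692 in TS and 10 for the average effect. Flk1 against ES gave 3704, TS against ES 2100 and the interaction 388. For H3K27me3 it was 1880 in ES, 3666 in Flk1, 2286 in TS and 2497 for the average effect. Flk1 against ES gave 4638, TS against ES 3789 and the interaction 2703. The correlation of WT and TKO cell-type differences was 0.432 for H3K4me2 Flk1 against ES, 0.612 for H3K4me2 TS against ES, 0.569 for H3K9me2 Flk1 against ES, 0.621 for H3K27me3 Flk1 against ES and 0.681 for H3K27me3 TS against ES. Between cell types the knockout effects correlated at 0.160 for H3K4me2 ES and Flk1, 0.188 for H3K4me2 ES and TS, 0.554 for H3K4me2 Flk1 and TS, 0.258 for H3K9me2 ES and TS, -0.0112 for H3K9me2 Flk1 and TS, 0.372 for H3K27me3 ES and Flk1, 0.401 for H3K27me3 ES and TS and 0.280 for H3K27me3 Flk1 and TS. Between marks the knockout effects correlated at 0.272 for H3K4me2 and H3K9me2 in Flk1, -0.216 for H3K4me2 and H3K9me2 in TS and -0.00512 for H3K9me2 and H3K27me3 in TS. The median change at the genes with the most mark in WT was -0.42 for H3K4me2 in ES, -0.16 for H3K9me2 in ES, 0.10 for H3K9me2 in TS and -0.33 for H3K27me3 in TS. The difference of the spread was then -0.0090 for H3K27me3 (exact permutation p = 0.870) and 0.073 for H3K9me2 (exact permutation p = 0.0556).

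With arrays scaled to the same spread the number of called genes was 1964 for H3K4me2 average effect, 5637 for H3K9me2 in Flk1, 3471 for H3K9me2 in TS and 864 for H3K9me2 average effect. The correlation of WT and TKO cell-type differences was 0.574 for H3K4me2 Flk1 against ES, 0.649 for H3K4me2 TS against ES, 0.655 for H3K9me2 Flk1 against ES, 0.650 for H3K27me3 Flk1 against ES and 0.720 for H3K27me3 TS against ES. Between cell types the knockout effects correlated at 0.0134 for H3K4me2 ES and Flk1, 0.315 for H3K4me2 Flk1 and TS, 0.574 for H3K27me3 ES and Flk1 and 0.405 for H3K27me3 ES and TS. Between marks the knockout effects correlated at -0.0631 for H3K4me2 and H3K27me3 in ES, 0.129 for H3K4me2 and H3K27me3 in TS, 0.307 for H3K4me2 and H3K9me2 in ES, 0.0107 for H3K4me2 and H3K9me2 in Flk1, -0.0888 for H3K4me2 and H3K9me2 in TS and 0.244 for H3K9me2 and H3K27me3 in ES. The median change at the genes with the most mark in WT was -0.12 for H3K4me2 in ES, -0.016 for H3K4me2 in Flk1, -0.071 for H3K4me2 in TS, 0.058 for H3K9me2 in TS, 0.12 for H3K27me3 in Flk1 and -0.23 for H3K27me3 in TS.

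With the median over probes 1894 genes were called for H3K9me2 in Flk1 and 277 for H3K9me2 average effect. The correlation of WT and TKO cell-type differences was 0.670 for H3K4me2 Flk1 against ES, 0.667 for H3K4me2 TS against ES, 0.642 for H3K27me3 Flk1 against ES and 0.693 for H3K27me3 TS against ES. Between marks the knockout effects correlated at -0.332 for H3K4me2 and H3K9me2 in TS. The median change at the genes with the most mark in WT was -0.53 for H3K4me2 in ES.

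With bright probes alone the correlation of WT and TKO cell-type differences was 0.696 for H3K4me2 TS against ES, 0.696 for H3K27me3 Flk1 against ES and 0.701 for H3K27me3 TS against ES. Between cell types the knockout effects correlated at 0.588 for H3K27me3 ES and Flk1, 0.367 for H3K27me3 ES and TS and 0.442 for H3K27me3 Flk1 and TS. Between marks the knockout effects correlated at 0.266 for H3K4me2 and H3K27me3 in Flk1, 0.101 for H3K4me2 and H3K27me3 in TS, -0.386 for H3K4me2 and H3K9me2 in TS and 0.0401 for H3K9me2 and H3K27me3 in TS. The median change at the genes with the most mark in WT was -0.12 for H3K9me2 in TS and -0.40 for H3K27me3 in TS.

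With the deposited log-ratio table the correlation of WT and TKO cell-type differences was 0.679 for H3K27me3 Flk1 against ES. Between cell types the knockout effects correlated at 0.564 for H3K27me3 ES and Flk1, 0.396 for H3K27me3 ES and TS and 0.418 for H3K27me3 Flk1 and TS. Between marks the knockout effects correlated at -0.374 for H3K4me2 and H3K9me2 in TS. The median change at the genes with the most mark in WT was -0.37 for H3K4me2 in ES and -0.16 for H3K9me2 in TS.

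With slides as random blocks 1972 genes were called for H3K9me2 in Flk1 and 142 for H3K9me2 average effect.

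With replicate number as a block 262 genes were called for H3K9me2 average effect.

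With scan day as a block the number of called genes was 0 for H3K9me2 in Flk1 and 1 for H3K9me2 average effect.

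With the arrays of the 2 groups alone 756 genes were called for H3K9me2 in ES.

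Lists whose direction turned were, with normexp background correction, for H3K9me2 in TS, germline (adjusted p = 1.2e-05, 1.2e-05 to 0.942 over its alternatives), housekeeping (adjusted p = 0.0188, 0.00414 to 0.987 over its alternatives), imprinted (adjusted p = 0.413, 0.00564 to 0.592 over its alternatives), endoderm (adjusted p = 0.0492, 0.0492 to 0.962 over its alternatives), stromal (adjusted p = 0.326, 0.00346 to 0.782 over its alternatives) and tissue-restricted (adjusted p = 0.0316, 0.0287 to 0.927 over its alternatives), and for H3K9me2 TS against ES, housekeeping (adjusted p = 0.732, 2.5e-04 to 0.732 over its alternatives) and stromal (adjusted p = 0.899, 0.00765 to 0.899 over its alternatives). With arrays scaled to the same spread they were, for H3K4me2 in ES, stromal (adjusted p = 0.866, 0.00811 to 0.918 over its alternatives), and for H3K9me2 Flk1 against ES, developmental (adjusted p = 0.00124, 0.00124 to 0.996 over its alternatives), and for H3K9me2 in TS, germline (adjusted p = 0.00129, 1.2e-05 to 0.942 over its alternatives) and housekeeping (adjusted p = 0.987, 0.00414 to 0.987 over its alternatives). These ranges include fry, which tests a list against no change in place of other genes. Its direction can therefore differ from camera's without a turn, as it did for H3K9me2 in TS, trophoblast (adjusted p = 0.0310, 0.0310 to 0.942 over its alternatives).

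With each array left out in turn, where a lone array was assumed to vary like those of the other groups, the number of called genes ranged from 5875 to 6589 for H3K4me2 in ES, from 2083 to 2501 for H3K4me2 in Flk1, from 3505 to 4365 for H3K4me2 in TS, from 6024 to 6483 for H3K4me2 Flk1 against ES, from 6480 to 7038 for H3K4me2 TS against ES, from 2656 to 4413 for H3K4me2 average effect, from 5914 to 6956 for H3K4me2 interaction, from 2304 to 3541 for H3K9me2 in ES, from 501 to 2278 for H3K9me2 in Flk1, from 3289 to 3966 for H3K9me2 in TS, from 6994 to 8332 for H3K9me2 Flk1 against ES, from 6190 to 7283 for H3K9me2 TS against ES, from 92 to 899 for H3K9me2 average effect, from 5664 to 7792 for H3K9me2 interaction, from 4918 to 5559 for H3K27me3 in ES, from 7306 to 8407 for H3K27me3 in Flk1, from 5638 to 6355 for H3K27me3 in TS, from 6916 to 7270 for H3K27me3 Flk1 against ES, from 7932 to 8322 for H3K27me3 TS against ES, from 5395 to 5943 for H3K27me3 average effect and from 7253 to 8596 for H3K27me3 interaction. Single arrays moved the count by more than 1.5 times for H3K4me2 in Flk1 and TS cells and its average effect, with the counts given above. For H3K9me2 they did so in ES, Flk1 and TS cells, with the counts given above. For the H3K9me2 average effect 10 of 12 arrays did: ES WT replicate 2 (899), ES TKO replicate 2 (332), Flk1 WT replicates 1 and 2 (183, 92), Flk1 TKO replicates 1 and 2 (206, 207), TS WT replicates 1 and 2 (99, 112) and TS TKO replicates 1 and 2 (123, 106).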

Other observations

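All tests in this part were chosen after the result was seen.

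The family of olfactory receptor genes, smell receptors silent outside the nose, had 657 measured members. For H3K9me2 in TKO ES cells 14 of them rose, 299 fell and 344 did not pass, and for H3K27me3 in TKO TS cells 98 rose, 419 fell and 140 did not pass. In WT cells the family's median stood at 1.11 for H3K9me2 in ES and at 0.83 for H3K27me3 in TS cells, against 0.71 and 0.32 in TKO cells.

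A hypothesis is that the whole family loses the mark in these 2 comparisons beyond what its base composition gives. Against genes of like GC and CpG content, 10 for each member, the family's median change was lower by a difference of -0.26 for H3K9me2 in ES cells (-0.35 to -0.18 over pairs of arrays), -0.29 with arrays scaled to the same spread and -0.13 with normexp background correction. For H3K27me3 in TS cells the difference was -0.52 (-0.53 to -0.46), -0.37 with scaling and -0.17 with normexp background correction. Both values fit the hypothesis, which was found and tested on the same arrays, and in ES cells the medium may contribute. The other comparisons were mixed. For H3K9me2 the difference was 0.073 in Flk1 cells (0.037 with scaling and 0.078 with normexp background correction), where 61 members rose and 4 fell, and -0.11 in TS cells, but -0.012 with scaling and 0.024 with normexp background correction. For H3K27me3 it was -0.13 in ES cells (-0.15 to -0.074 over pairs of arrays), -0.14 with scaling and -0.042 with normexp background correction. In Flk1 cells it was -0.28 (-0.37 to -0.21), -0.37 with scaling and 0.00095 with normexp background correction. For H3K4me2 it was -0.16 in ES cells (-0.21 to -0.10), where 45 members rose and 138 fell, -0.73 with scaling and -0.066 with normexp background correction. In Flk1 cells it was 0.14 (0.16 to 0.20), where 184 rose and 21 fell, 0.073 with scaling and 0.19 with normexp background correction. In TS cells it was 0.078 (0.071 to 0.093), where 150 rose and 26 fell, -0.24 with scaling and 0.050 with normexp background correction.

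A further hypothesis is that H3K27me3 changes in TKO cells follow CpG density where the mark was low in WT ES cells. Across 6321 such genes, which are not independent replicates, Spearman rho between the change in Flk1 cells and CpG density was 0.248 (0.177 to 0.300 over pairs of arrays). It was 0.241 in TS cells, and ES cells were left out because their WT arrays chose the genes. Across the 6321 genes with more of the mark it was 0.0289 in Flk1 and -0.0652 in TS cells. Falls at CpG-poor genes would give the same rho. Whether CpG-rich genes rose was not tested, nor was DNA methylation measured.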
